A study of Mus musculus with 6 samples.

How the data were processed

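Total RNA from 6 samples of primary mouse vascular smooth muscle cells, 3 transfected with siScrambled and 3 with siPfkfb3 at 20 nM for 48 h, was extracted with TRIzol and made into mRNA sequencing libraries, per the labels' protocols. Reads were aligned with HISAT2 to GRCm38/mm10, per the submitters' processing notes; the HISAT2 version, the counting tool, whether counting used strand, and the annotation release are not given in the sources used here. The authors deposited 1 table of FPKM (fragments scaled to gene length and to the mapped fragments of the library, named so in the file header) with 1 column per sample and 24970 rows. Of these, 22036 are Ensembl mouse genes and 2934 are rows the authors named as new genes. Symbols were found for 22022 of the 22036 Ensembl IDs in the table of gene names of the reference. Group and replicate were taken from the sample titles. The genotype labels of siPfkfb3 replicates 2 and 3 name PFKFB4 and PFKFB5; the titles were followed, and Pfkfb1, Pfkfb2 and Pfkfb4 were read in every library.

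FPKM divides out both depth and gene length, so no counts and no counting intervals can be given, and tests that need counts were not run. Relative depth was read from the commonest value above 0 among the new-gene rows of each library, 0.139 to 0.173 FPKM, shared by 20 to 36 rows. The deepest library then came out 1.24 times as deep as the shallowest. Over the 172 rows that hold the value in any library, 80% of 220 values above 0 were whole multiples of it, within a tolerance of 0.002 of a multiple. These rows were chosen for holding the value, so most of those multiples were fixed by the choice. The share therefore cannot check the relative depth, which is a rough estimate. It rests on rows of similar length and gives no read number. An exact 0 can be a failed estimate and was not read as absence.

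Genes with a mean of at least 1 FPKM over the 6 samples (11240 genes, 308 of them new-gene rows) were tested on log2(FPKM + 1), with a pseudocount of 1, by limma 3.58.1 in R 4.3.3 with an intensity trend and a robust fit, two-sided, and Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes are siPfkfb3 minus siScrambled on that scale, which understates the change of low genes. Every adjusted p for a gene is from this fit unless another is named. Pfkfb3 was also tested with the exact permutation test. There were 29 gene lists written from textbook knowledge before the data were examined; the 26 with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over these lists, and read beside camera with an estimated correlation and fry. Older symbols of list members were looked up through RefSeq synonyms.

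The genes named in the text were chosen by a rule also written before the data were examined. It takes Pfkfb3 with Pfkfb1, Pfkfb2 and Pfkfb4, then the 12 largest changes in each direction among called genes whose groups do not overlap, whose higher group mean is at least 5 FPKM and whose symbol is not a clone, accession or model name. In each list it takes up to 4 called members with the largest absolute change, or, where none is called, the 2 with the highest mean. Not every gene the rule takes is named, and genes named outside it are marked where they appear. Gene positions, exons and 3′ UTRs are from the GENCODE M21 annotation of GRCm38, the build of the submitters' notes. Of the 125 genes the rule takes, exons of 37 overlap those of another gene.

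The 3′ UTR search, added after the data had been seen, took the protein-coding transcript with the longest 3′ UTR of at least 30 bases, which 10857 of the tested genes (96.6%) have. Each of 16088 heptamers found in at least 50 genes was scored by a linear model of the ranked fold change on its presence, with the length and GC content of the 3′ UTR as covariates, against 100 shuffles of the fold changes. Genes were also counted without carriers of any of the 13 heptamers whose absolute z passed the largest of the shuffles. Medians carry 95% bootstrap intervals from 2000 draws. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures matplotlib 3.10.9.

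The limma step was tested on simulated values for the 11240 genes with the means of the real table. The noise was normal, with a spread that followed the trend of the real spread over the mean. Of 100 genes changed by 0.5 and 100 changed by 1 on the log2 scale, all 100 and 100 were recovered, and 9 of 209 calls were unchanged genes. Genes noisier than the trend were not simulated, and far fewer genes were changed than were called in the real table. Recovery in the real table can therefore be lower. The list test and the heptamer search also recovered planted effects. Alternatives set before the data were examined were pseudocounts of 0.1 and 0.5, other filters on low values, rescaling to TPM, trimmed-mean (TMM) scaling, quantile normalization, limma without trend and robust fit, the replicate number as a block, thresholds on fold size, each replicate left out, and the other list tests. Added after seeing the data were a fit without some heptamer carriers, a fit without the new-gene rows, and 3 further gene lists. The first of these left out genes whose 3′ UTR carries GAAGAAC, CGGAGAA, TCGGAGA or TGTCACG, only some of the heptamers past the shuffles.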

Results

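RNA was sequenced from primary mouse vascular smooth muscle cells, the contractile cells of the arterial wall, grown in culture from C57BL/6 male mice. The cells were transfected for 48 h with 20 nM of a scrambled control siRNA (siScrambled, 3 samples) or of siRNA against Pfkfb3 (siPfkfb3, 3 samples). An siRNA is a short RNA duplex that directs cleavage of an mRNA it matches. Pfkfb3 encodes an enzyme that makes fructose 2,6-bisphosphate, an activator of the glycolytic enzyme phosphofructokinase. The comparison asks which transcripts differ when Pfkfb3 is depleted. Pfkfb3 fell to 44.9% of its control level, from 3.97 ± 0.0949 to 1.78 ± 0.138 FPKM (mean ± SD, n = 3 each). Of 30 tested genes of the interferon response 26 rose and none fell, with Ifi44 going from 2.28 ± 0.868 to 19.3 ± 5.33 FPKM. All 25 tested genes of the cell cycle and mitosis fell, by a median of 0.65 on the log2 scale. Col2a1, the collagen of cartilage, rose from 56.0 ± 3.71 to 158 ± 12.9 FPKM, and the chemokine Ccl2 fell from 11.5 ± 0.885 to 3.51 ± 0.439 FPKM.

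Each library was deposited as FPKM, fragments scaled to gene length and library size, so the number of reads is unknown. The commonest value among the new-gene rows put the libraries' relative depth within a factor of 1.24 of each other. This is a rough estimate without an independent check. Between 11189 and 11247 genes reached 1 FPKM in a library. Transcripts of the mitochondrial genome made up 6.48% to 7.35% of the summed FPKM. Ribosomal protein transcripts made up 7.57%, 7.09% and 7.50% in siScrambled and 6.93%, 6.47% and 6.76% in siPfkfb3, groups that did not overlap. Pairs of libraries correlated across genes at 0.993 to 0.995 within a group and at 0.979 to 0.983 between groups (genes are not independent replicates). The design text calls the samples different cells but does not say that they came from separate animals or isolations, so p-values measure only the spread between these samples, which may be technical.

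Pfkfb3 (chromosome 2, 11471433 to 11554077, minus strand, ENSMUSG00000026773; GRCm38) was the targeted gene. It stood at 4.03, 4.02 and 3.86 FPKM in siScrambled replicates 1 to 3 and at 1.92, 1.65 and 1.77 FPKM in siPfkfb3 replicates 1 to 3, so that the siPfkfb3 mean was 44.9% of the control mean. All 3 siPfkfb3 values lay below all 3 controls. On the log2(FPKM + 1) scale, which understates changes of genes this low, the change was −0.84 ± 0.07 (SE; limma, adjusted p = 2.66e-05). The exact two-sided permutation test gave p = 0.1, the smallest value that 3 against 3 samples allow. The longest annotated 3′ UTR of Pfkfb3 holds 1 copy of the heptamer CGGAGAA, whose carriers tended to be higher in siPfkfb3 (median log2 fold change 0.12 over 278 genes). The genotype labels of siPfkfb3 replicates 2 and 3 name PFKFB4 and PFKFB5 rather than PFKFB3, while their titles name PFKFB3. The paralogs differed by less than the test could separate: Pfkfb1 (−0.07) went from 1.30 ± 0.102 to 1.18 ± 0.0915 FPKM (mean ± SD, n = 3 each; limma, adjusted p = 0.537), Pfkfb2 (−0.04) from 4.54 ± 0.423 to 4.38 ± 0.288 FPKM (adjusted p = 0.718), and Pfkfb4 (−0.12) from 1.88 ± 0.268 to 1.66 ± 0.257 FPKM (adjusted p = 0.417).

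**Figure D1:**
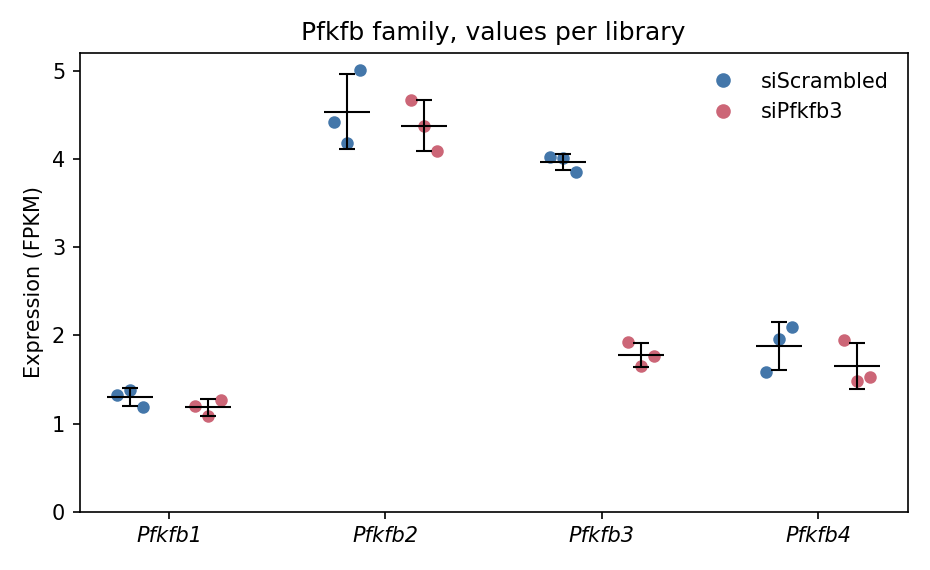
Expression of the Pfkfb genes in FPKM (vertical axis) in each of the 3 siScrambled and 3 siPfkfb3 libraries. Points are libraries, and bars are the mean ± SD; Pfkfb3 is at 1.65 to 1.92 FPKM in siPfkfb3 and at 3.86 to 4.03 FPKM in siScrambled.

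Of 11240 genes with a mean of at least 1 FPKM, 4079 (36.3%) passed the limma test, 1775 higher and 2304 lower in siPfkfb3. Most changes were small: the median absolute log2 fold change of the called genes was 0.31, and 93 genes (53 higher, 40 lower) moved by at least 1. The groups did not overlap for 4046 of the called genes and for 49.5% of all tested genes, where chance alone gives 10%. The genes named here follow a rule set before the data were examined: the 12 largest changes in each direction among called, non-overlapping genes of at least 5 FPKM. The values that follow are means ± SD in FPKM, siScrambled first, with n = 3 in each group.

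Genes induced by interferon, the antiviral cytokine, made up most of the upper end. Ifi44 (chromosome 3, 151730922 to 151749960, minus strand, ENSMUSG00000028037), an interferon-induced gene, rose from 2.28 ± 0.868 to 19.3 ± 5.33 FPKM (log2 fold change 2.63 ± 0.26 SE, adjusted p = 0.00107). Ifit3 rose from 42.7 ± 13.7 to 165 ± 43.3 and Ifit3b from 12.9 ± 2.65 to 45.5 ± 11.9 FPKM, by 1.94 and 1.73 on the log2 scale (adjusted p = 0.0109 and 0.00404). Irf7, a transcription factor of the interferon response, rose from 8.09 ± 1.91 to 26.7 ± 5.86 FPKM (log2 fold change 1.61 ± 0.22 SE, adjusted p = 0.00391), and Zbp1, a sensor of left-handed nucleic acids, rose from 5.62 ± 2.03 to 18.8 ± 4.76 (log2 fold change 1.60 ± 0.30 SE, adjusted p = 0.0132). Zbp1 missed the threshold when siScrambled replicate 3 or siPfkfb3 replicate 1 was left out (adjusted p = 0.0504 and 0.0543). Bst2, a membrane protein that tethers virions, rose from 89.9 ± 19.6 to 265 ± 26.8 FPKM (log2 fold change 1.56 ± 0.19 SE, adjusted p = 0.00329). Oasl2, Usp18 and Ifit1 rose by 1.64, 1.55 and 1.52, and Gbp3, a guanylate-binding protein, also rose (adjusted p = 0.00702). The remaining members were H2-Q4, a class I histocompatibility gene, at 5.39 ± 0.603 and 17.4 ± 3.21 FPKM (log2 fold change 1.51 ± 0.13 SE, adjusted p = 0.000140), and Col2a1 (chromosome 15, 97975602 to 98004695, minus strand, ENSMUSG00000022483), which encodes the major collagen of cartilage and rose from 56.0 ± 3.71 to 158 ± 12.9 FPKM (log2 fold change 1.48 ± 0.07 SE, adjusted p = 2.31e-06).

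At the lower end, Clca3a2 (chromosome 3, 144796559 to 144819494, minus strand, ENSMUSG00000028262), of the calcium-activated chloride channel regulator family, fell from 6.78 ± 0.784 to 0.957 ± 0.251 FPKM (log2 fold change −1.99 ± 0.11 SE, adjusted p = 1.89e-06). Aqp1 (chromosome 6, 55336432 to 55348555, plus strand, ENSMUSG00000004655), a water channel, fell from 21.5 ± 1.18 to 6.85 ± 0.674 FPKM (log2 fold change −1.52 ± 0.07 SE, adjusted p = 8.67e-07). Ccl2 (chromosome 11, 82035571 to 82037453, plus strand, ENSMUSG00000035385), a chemokine that attracts monocytes, fell from 11.5 ± 0.885 to 3.51 ± 0.439 FPKM (log2 fold change −1.48 ± 0.08 SE, adjusted p = 2.36e-06). Efemp1, an extracellular matrix protein of the fibulin family, fell from 48.2 ± 0.819 to 19.7 ± 0.943 FPKM (log2 fold change −1.25 ± 0.04 SE, adjusted p = 2.80e-07), and Aurkb, a mitotic kinase, fell from 9.34 ± 0.831 to 3.43 ± 0.405 FPKM (log2 fold change −1.23 ± 0.09 SE, adjusted p = 7.86e-06). Uxs1, which makes UDP-xylose, fell from 17.0 ± 1.09 to 5.92 ± 0.361 (log2 fold change −1.38 ± 0.06 SE, adjusted p = 8.67e-07), and Rnf7, a subunit of ubiquitin ligases, from 38.6 ± 0.581 to 15.0 ± 1.61 FPKM (log2 fold change −1.31 ± 0.07 SE, adjusted p = 1.30e-06). Ptgs1, a cyclooxygenase of prostaglandin synthesis, fell by 1.21 on the log2 scale (adjusted p = 3.93e-06). Ermp1, Diras2, Nkain4 and Susd2 changed by −1.48, −1.42, −1.23 and −1.23.

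A search of 3′ UTRs was added after the fold changes had been seen. Among the 12 lowest genes, Ermp1, Uxs1, Rnf7 and Aurkb carry the heptamer GAAGAAC in their longest 3′ UTR, 4 of 12 against 11.0% of the 10857 genes searched, and none of the 12 highest does. On the higher side 10 heptamers passed the largest z of the shuffles, but only CGGAGAA, TCGGAGA and TGTCACG were looked up in single genes. These occur in Oasl2 and Ermp1, 1 gene of each set of 12, against 6.87% of all genes searched. Below, a heptamer of the higher side means any of these. Ifit3 with Ifit3b, H2-Q4, Gbp3 and Clca3a2 have close relatives in the genome, and exons of Irf7, Usp18, H2-Q4, Clca3a2, Nkain4 and Ptgs1 overlap a gene on the opposite strand, so their values are uncertain.

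**Figure D2:**
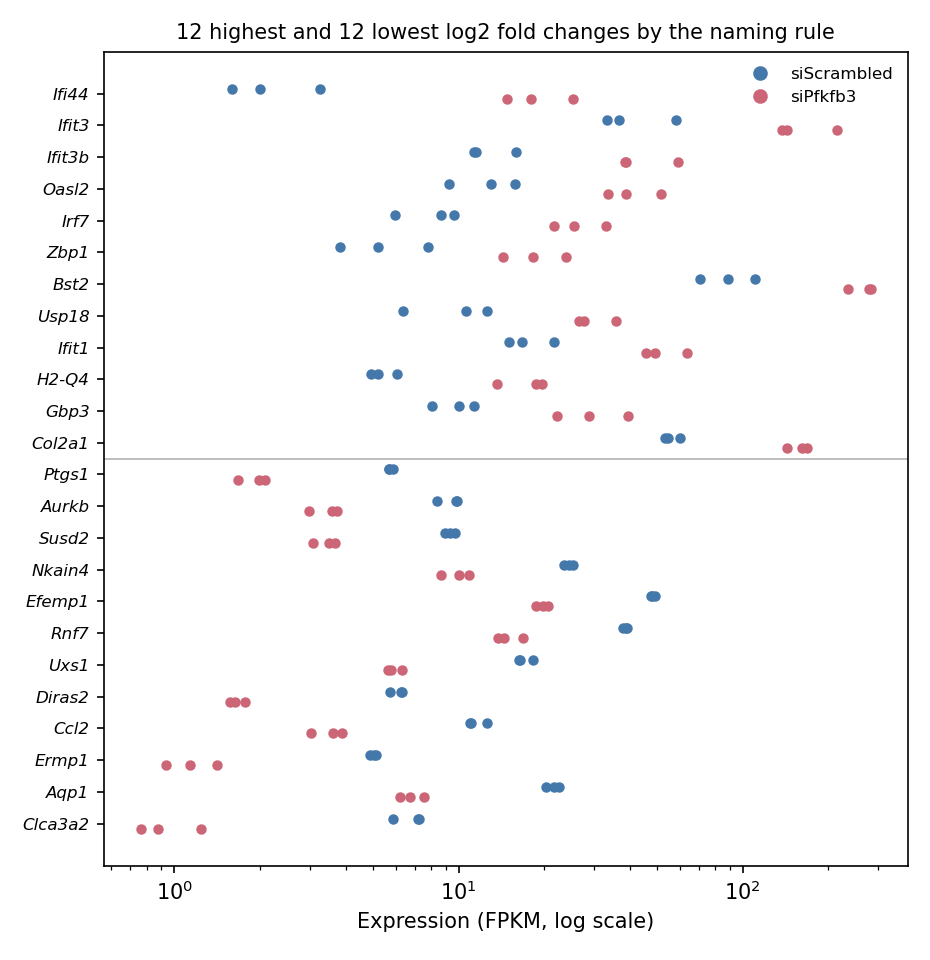
Expression in FPKM (horizontal axis, log scale) of the 12 highest and the 12 lowest genes by the naming rule, each point a library, siScrambled in blue and siPfkfb3 in red. The groups do not overlap for any of these genes; Ifi44 averaged 19.3 ± 5.33 FPKM in siPfkfb3 and 2.28 ± 0.868 FPKM in siScrambled (mean ± SD).

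Gene lists fixed before the data were examined were tested with camera, which compares a list's members with all other genes, at a preset correlation of 0.01 between genes. It called 10 of the 26 lists that had at least 5 tested members. With an estimated correlation it called 0 of the 26, and fry, which asks only whether a list's own members move, on balance, one way, called 21.

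Of 30 tested interferon response genes, 26 rose, none fell and 4 were not called (27 higher adjusted over the list alone), with a median log2 fold change of 1.14. Rsad2 (0.70), Cxcl10 (0.87), Gbp2 (0.47) and Isg20 (0.24) did not pass, and are named after their values were seen. Camera gave adjusted p = 1.85e-14, and adjusted p = 0.385 with an estimated correlation. Within the list, levels varied between libraries of one group: the mean log2(FPKM + 1) was 3.43, 3.01 and 3.18 in siScrambled and 4.26, 4.23 and 4.69 in siPfkfb3. The 3 tested macrophage and leukocyte markers were not called on the deposited scale; among them Lyz2, a lysozyme of macrophages, stood at 12.2 ± 0.0970 and 13.4 ± 0.312 FPKM (adjusted p = 0.0563), groups that did not overlap and that passed the test under TPM, TMM and quantile scaling (adjusted p = 0.0375, 0.0331 and 0.0416), and Cd14 at 1.04 ± 0.493 and 1.52 ± 0.322 FPKM (adjusted p = 0.205). Of 19 cytokine, chemokine and NF-kB genes, 5 rose and 6 fell (7 lower adjusted over the list alone; camera, adjusted p = 0.574). Besides Ccl2, the adhesion molecule Vcam1 fell by 0.73 on the log2 scale, from 212 ± 5.58 to 127 ± 2.98 FPKM, while the chemokines Ccl7 (0.57) and Ccl5 (0.54) rose.

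All 25 cell cycle and mitosis genes fell (25 adjusted over the list alone), with a median log2 fold change of −0.65 (camera, adjusted p = 1.85e-14; adjusted p = 0.145 with an estimated correlation). Mki67, a marker of proliferating cells, fell from 19.2 ± 1.75 to 10.8 ± 0.315 FPKM (log2 fold change −0.78 ± 0.07 SE, adjusted p = 2.22e-05). Prc1, of the mitotic spindle, and Ccnb1, the cyclin of mitotic entry, changed by −0.78 and −0.76. Of 27 DNA replication genes, 22 fell and none rose (23 lower adjusted over the list alone), with a median of −0.33 (camera, adjusted p = 6.96e-09; adjusted p = 0.320 with an estimated correlation). Tk1, thymidine kinase, went from 19.1 ± 0.875 to 9.17 ± 0.0799 FPKM (log2 fold change −0.98 ± 0.05 SE, adjusted p = 1.31e-06). Rrm2, a subunit of ribonucleotide reductase, changed by −0.77, and the helicase subunit Mcm5 by −0.74. In the same samples 10 of 16 adventitial fibroblast markers fell and 4 rose.

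In glycolysis, the pathway Pfkfb3 regulates, 11 of 17 tested genes fell and none rose (11 lower adjusted over the list alone), with a median log2 fold change of −0.20 (camera, adjusted p = 0.00267; adjusted p = 0.385 with an estimated correlation). Hk1, a hexokinase, fell from 27.5 ± 1.80 to 18.1 ± 0.249 FPKM (log2 fold change −0.57 ± 0.05 SE, adjusted p = 3.65e-05). Eno2, an enolase, and Pgk1, phosphoglycerate kinase, changed by −0.40 and −0.34. Ldha, which makes lactate, went from 239.9 ± 11.2 to 195 ± 3.69 FPKM (log2 fold change −0.29 ± 0.04 SE, adjusted p = 0.000275). Of 10 pentose phosphate genes, 1 rose and 3 fell, and camera did not call the list (adjusted p = 0.770). Its median was −0.13 but its mean 0.04, since Taldo1, transaldolase, rose (log2 fold change 1.31 ± 0.05 SE, adjusted p = 4.85e-07); fry gave the upward direction and camera the downward. G6pdx, the first enzyme of the pathway, Tkt, transketolase, and Prps2 changed by −0.29, −0.26 and −0.19, Prps2 only just (adjusted p = 0.0494): its call ended in 11 other settings, among them TPM, TMM and quantile scaling and 5 of the 6 fits that leave out a library (adjusted p of 0.0523 to 0.164). Taldo1 carries a heptamer of the higher side in its 3′ UTR, and Hk1 and Prps2 carry GAAGAAC. In the hexosamine and O-GlcNAc list 5 of 11 genes rose and none fell (camera, adjusted p = 0.0362; adjusted p = 0.320 with an estimated correlation). They included Gfpt1, the entry enzyme of the pathway (0.21), Pgm3 (0.36), Gnpnat1 (0.41) and Renbp (0.41). The call of Gnpnat1 ended without a filter on low values (adjusted p = 0.0655) and without siScrambled replicate 2 or 3 or siPfkfb3 replicate 1 or 3 (adjusted p of 0.0592 to 0.0650).

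Of 32 nuclear-encoded oxidative phosphorylation genes, 10 fell and 2 rose (camera, downward, adjusted p = 0.0361; adjusted p = 0.524 with an estimated correlation), with Cox7c at −0.27, Uqcrq at −0.33 and Ndufa2 at −0.33. The call of Ndufa2 (adjusted p = 0.0487) ended in 11 other settings (adjusted p of 0.0503 to 0.141) and that of Uqcrq in 4 (adjusted p of 0.0538 to 0.0706). Camera did not call the citric acid cycle list, where 3 of 29 genes rose, Pdk4 (0.47) and Idh1 (0.44) among them, and 8 fell, including Dlst (−0.35) and Pcx (−0.31) (adjusted p = 0.206). Fatty acid oxidation was not called either (adjusted p = 0.276): 1 of 22 genes rose and 7 fell, with Acadm, a medium-chain dehydrogenase and a carrier of GAAGAAC, at −0.48, Cpt1a at −0.29, Acaa2 at −0.27 and Hadha at −0.25. Of 24 cholesterol synthesis genes, 7 rose and 1 fell (camera, adjusted p = 0.0452; adjusted p = 0.385 with an estimated correlation). Insig1, a sterol-regulated protein of the endoplasmic reticulum that carries a heptamer of the higher side, rose from 33.6 ± 2.26 to 67.6 ± 2.37 FPKM (log2 fold change 0.99 ± 0.05 SE, adjusted p = 1.33e-06). Stard4 and Fdps rose by 0.46 and 0.45. The calls of the hexosamine, oxidative phosphorylation, cholesterol and TGF-beta lists ended when siPfkfb3 replicate 2 was left out, with adjusted p of 0.0701, 0.108, 0.0847 and 0.0573. Each of these calls also ended without at least 1 other library: cholesterol without siScrambled replicate 1 or 2 or siPfkfb3 replicate 3 (adjusted p = 0.0738, 0.0738 and 0.0641), oxidative phosphorylation without siScrambled replicate 1 or 3 (adjusted p = 0.101 and 0.0732), hexosamine without siScrambled replicate 3 (adjusted p = 0.0540) and TGF-beta without siPfkfb3 replicate 3 (adjusted p = 0.0523). Cholesterol was also not called at a mean of at least 5 FPKM (adjusted p = 0.0818). The hexosamine and cholesterol calls also ended without the genes that carry GAAGAAC or a heptamer of the higher side (adjusted p = 0.0590 and 0.108).

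Of 24 genes of the ATF4 and unfolded protein response, 14 fell and 1 rose (15 lower adjusted over the list alone; camera, adjusted p = 0.00386; adjusted p = 0.320 with an estimated correlation). The 4 with the largest changes were targets of ATF4. Psat1, of serine synthesis, fell from 62.5 ± 1.59 to 33.5 ± 0.263 FPKM (log2 fold change −0.88 ± 0.04 SE, adjusted p = 5.87e-07), and Mthfd2, Chac1 and Sesn2 changed by −0.50, −0.45 and −0.43. In the p53 target list 9 of 24 genes rose and 4 fell (10 higher adjusted over the list alone; camera, adjusted p = 0.204), with Pmaip1 at 0.85, Ei24 at 0.83, Tigar at 0.44 and Trp53inp1 at −0.60. Ei24 and Tigar carry a heptamer of the higher side, and Tigar also carries GAAGAAC. In the hypoxia list 4 of 19 genes rose and 4 fell (camera, adjusted p = 0.958), with Epas1 at −0.64, Ddit4 at −0.32, Ero1l at 0.34 and Kdm3a at 0.34; its median and mean were −0.01 and −0.03, while camera gave the upward direction. FoxO targets and autophagy genes counted 11 higher and 4 lower of 29 (5 lower adjusted over the list alone; camera, adjusted p = 0.206), with Irs2 at 0.74, Foxo4 at 0.52 and Klf2 at −0.88. Of 25 YAP, SRF and immediate early genes, 5 rose and 11 fell (6 higher adjusted over the list alone; camera, adjusted p = 0.191). The early response genes Ier2 (−1.01), Egr1 (−0.88), Dusp1 (−0.86) and Nr4a1 (−0.85) were the 4 with the largest changes; Dusp1 carries GAAGAAC, and Ier2 a heptamer of the higher side.

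Of 28 contractile smooth muscle genes, 8 rose and 3 fell (9 higher and 8 lower adjusted over the list alone), and camera did not call the list (adjusted p = 0.468; median −0.02, mean 0.02). Cald1, caldesmon, rose (log2 fold change 0.44 ± 0.04 SE, adjusted p = 2.67e-05). Mylk, the kinase of myosin light chains, and the integrin Itga8 rose by 0.35 and 0.36, and Cdh13 fell by 0.46 on the log2 scale. Cald1 carries a heptamer of the higher side and Cdh13 carries GAAGAAC. Of 18 osteogenic and mineralization genes, 6 rose and 1 fell (camera, adjusted p = 0.0110; adjusted p = 0.320 with an estimated correlation). The risers named by the rule are genes of cartilage or matrix and a decoy receptor: Col2a1, Col10a1 (1.15), a collagen of hypertrophic cartilage, Postn (0.66), a secreted matrix protein, and Tnfrsf11b (osteoprotegerin), which rose from 119 ± 3.79 to 236 ± 5.63 FPKM (log2 fold change 0.98 ± 0.03 SE, adjusted p = 2.57e-07). Runx2, the osteoblast transcription factor, named after its value was seen, stood at 3.53 ± 0.372 and 4.02 ± 0.0709 FPKM (adjusted p = 0.156). Without a filter on low values, the osteogenic list was not called (adjusted p = 0.0709).

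Matrix genes moved both ways. Of 20 collagens, 6 rose and 10 fell (camera, adjusted p = 0.358), with Col11a1 at 0.85, Col5a2 at 0.59, Col12a1 at 0.52 and Col15a1 at −0.71. Elastic fibre and crosslinking genes counted 10 higher and 6 lower of 27 (camera, adjusted p = 0.204), with Mfap4 (0.70) and P4ha3 (0.56) higher and Loxl2 (−0.47) and Efemp1 lower. Of 25 proteoglycans and glycoproteins, 9 rose and 12 fell (camera, adjusted p = 0.358), with Aspn at 0.68, Sdc1 at −0.73, Prelp at −0.45 and Fmod at −0.43. Matrix proteases and their inhibitors counted 4 higher and 9 lower of 22 (10 lower adjusted over the list alone; camera, adjusted p = 0.212). Plat, a plasminogen activator, fell from 22.2 ± 1.13 to 9.10 ± 0.921 FPKM (log2 fold change −1.20 ± 0.07 SE, adjusted p = 2.87e-06). The metalloproteinase inhibitor Timp3 and Adam12 rose by 0.67 and 0.68. Aspn, Sdc1 and Adam12 carry GAAGAAC, and Timp3 and Adam12 a heptamer of the higher side. Of 24 TGF-beta signalling genes, 12 rose and 5 fell (camera, adjusted p = 0.0361; adjusted p = 0.385 with an estimated correlation), with Pmepa1 (0.64) higher and Tgfbi (−0.89), a carrier of GAAGAAC, and Id1 (−0.45) lower.

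Some markers of other cells that a vascular culture could hold also passed the test. Of 16 adventitial fibroblast markers, 4 rose and 10 fell (5 higher adjusted over the list alone; camera, adjusted p = 0.119; 0.0488 without a filter on low values). Cd34, a surface protein of progenitor cells, fell from 11.8 ± 0.290 to 5.17 ± 0.169 FPKM and Dpt, dermatopontin, from 57.4 ± 1.54 to 30.8 ± 2.45 FPKM, by 1.05 and 0.88 on the log2 scale, and Clec3b changed by −0.92; Cd34, like Lyz2 and Prx, carries a heptamer of the higher side. Penk, the enkephalin precursor, rose from 14.7 ± 3.21 to 33.3 ± 0.180 FPKM (log2 fold change 1.15 ± 0.13 SE, adjusted p = 0.000757). Schwann and neuronal markers counted 1 higher and 6 lower of 14 (camera, adjusted p = 0.206), with S100b at −0.84, Tubb3 at −0.39, Pmp22 at −0.31 and Prx at −0.28; the call of Prx ended without siScrambled replicate 2 or 3 or siPfkfb3 replicate 3 (adjusted p of 0.0507 to 0.0680). Of 6 adipocyte markers, 2 fell, Fabp4 (−0.36) and Pnpla2 (−0.31) (camera, adjusted p = 0.264). Too few members for a list test passed the expression filter in the endothelial list, where Erg (0.54) and Flt1 (0.26) both rose, and in the skeletal and cardiac muscle list, where 1 of 2 genes fell, Tnnt2, from 33.7 ± 1.80 to 15.6 ± 0.806 FPKM. Adjusted over the list alone, the counts of every list given here without such a count equalled those over all genes tested.

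Exons of Tkt, Fdps, Pfkfb2, Gnpnat1 and Loxl2 overlap a gene on the same strand, and those of Pfkfb1, Pfkfb2 and these list members one on the opposite strand, so their values are uncertain: Hk1, G6pdx, Gnpnat1, Pgm3, Ndufa2, Hadha, Ei24, Tigar, Vcam1, Itga8, Mylk, Col10a1, Col15a1, Mfap4, Loxl2, Aspn, Prelp, Timp3, Irs2, Dusp1, Prc1, Tk1, Penk, Cd34 and Prx.

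**Figure D3:**
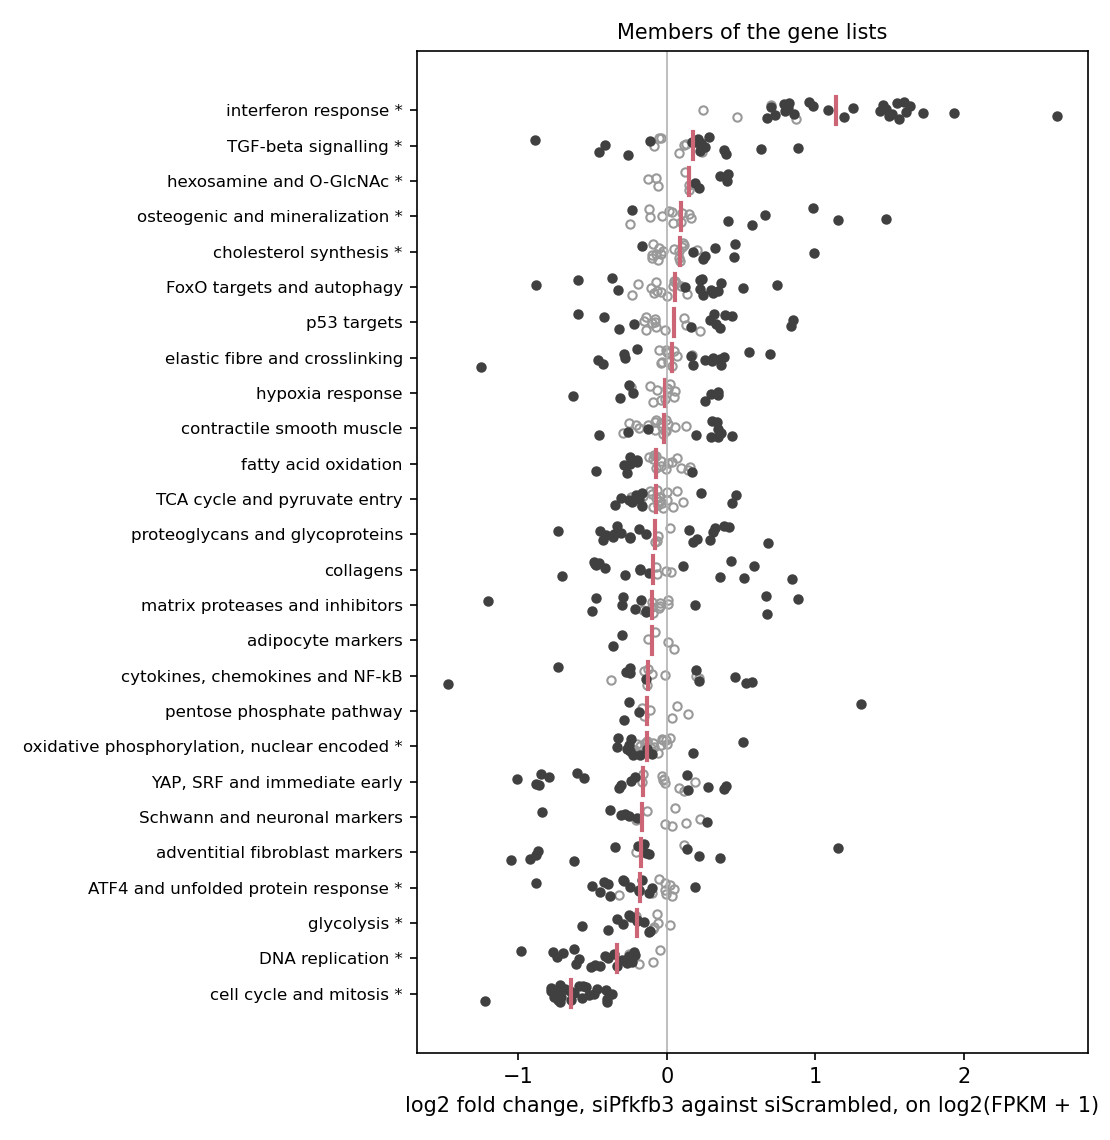
Log2 fold change of each tested member (horizontal axis, on the log2(FPKM + 1) scale, siPfkfb3 against siScrambled) in the 26 gene lists with a list test, sorted by median. Filled points passed the limma test, open points did not, red bars are medians, and an asterisk marks the 10 lists called by camera at the preset correlation; the cell cycle median is −0.65 and the interferon median 1.14.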

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

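The fits without heptamer carriers and without the new-gene rows were chosen after the results were seen. All other settings were set before the data were examined. Heptamer carriers are here the genes whose 3′ UTR holds GAAGAAC, CGGAGAA, TCGGAGA or TGTCACG, only some of the heptamers past the shuffles. The count of 4079 called genes stayed between 3274 (mean of at least 5 FPKM) and 4148 (mean of at least 0.5 FPKM) over the pseudocounts, filters, scalings and variance model, and was 3182 without heptamer carriers (9447 genes tested) and 4051 without new-gene rows. Leaving out one replicate gave 3320 to 3692 genes, 1451 to 1637 higher and 1869 to 2071 lower, with fewer samples in each fit. A fold threshold lowers the count by construction: 93 genes (53 higher, 40 lower) changed by at least 1 and 529 (249 higher, 280 lower) by at least 0.58. The share of calls that were higher was 43.5%, and at most 49.3% over the scalings (quantile normalization), which moved the median of all genes by no more than 0.02. Without a fold threshold, Pfkfb3 was called in every setting that tested it, at −0.88 to −0.80 with one replicate left out; at −0.84 it falls short of a threshold of 1, and it drops out at a mean of at least 5 FPKM and without heptamer carriers. Replicate numbers did not pair the samples: same-numbered deviations correlated at −0.11, 0.06 and 0.05, and 2 of 6 samples correlated best with their own number. With the replicate block 3907 genes (1680 higher, 2227 lower) and 8 lists were called, cholesterol synthesis and TGF-beta signalling missing the threshold (adjusted p = 0.0524 each) and Ifit3 too (adjusted p = 0.0707, cause not tested). The number of called lists was 9 at a mean of at least 5 FPKM (cholesterol synthesis lost, adjusted p = 0.0818), 9 without heptamer carriers (hexosamine and cholesterol lost, adjusted p = 0.0590 and 0.108; matrix proteases gained, 0.0478), 6 to 10 with one replicate left out (6 without siPfkfb3 replicate 2; the cause was not tested), 0 with camera at an estimated correlation and 21 with fry, which asks another question. Among the genes the naming rule takes and the tested lists, no call changed direction in any setting. The direction of other calls was not compared. Among single named genes, 39 gene and setting pairs lost a call, most often Ndufa2, Prps2, Gnpnat1 and Uqcrq, and 3 gained one, all of them Lyz2 under TPM, TMM and quantile scaling. DESeq2 and edgeR, planned only for counts, were not run. Unknown depth leaves the counting error of genes near 1 FPKM open.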

Other observations

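The tests in this part were chosen after the results they bear on had been seen, and so were their bounds, except the splits for the gene lists; the leukocyte test also replaced one on the 3 tested markers. The 3 gene lists used first were written after the leading genes had been seen (Upk3b, Nkain4, H2-Q4, Tap1, Col2a1 and Col10a1 among them), so their counts are not independent evidence. Of 17 tested genes of class I antigen presentation, 11 rose and none fell, with a median log2 fold change of 0.43 (camera, unadjusted p = 2.45e-05; unadjusted p = 0.219 with an estimated correlation). B2m, the light chain of class I molecules, rose from 692 ± 49.6 to 1007 ± 85.9 FPKM (mean ± SD, n = 3 each), H2-K1 from 60.1 ± 5.40 to 96.6 ± 8.31, and the peptide transporter Tap1 from 12.0 ± 0.948 to 26.0 ± 2.30 FPKM, by 0.54, 0.68 and 1.06 on the log2 scale, while Tap2 stood at 15.4 ± 0.635 and 16.3 ± 0.714 FPKM (limma, adjusted p = 0.267). Class I genes are close copies of each other, so their single values are uncertain.

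Of 12 cartilage matrix genes, 6 rose and 2 fell (camera, unadjusted p = 0.0461; unadjusted p = 0.229 with an estimated correlation). Acan, aggrecan, rose from 9.50 ± 0.660 to 14.7 ± 0.809 FPKM and Col11a1 rose by 0.85 on the log2 scale, beside Col2a1 and Col10a1, while Fmod and Epyc fell and Sox9, the cartilage transcription factor, stood at 12.4 ± 0.899 and 12.6 ± 1.19 FPKM (limma, adjusted p = 0.916). Of the 19 mesothelial markers listed, only 5 passed the expression filter. All 5 fell, with a median of −0.84 (camera, unadjusted p = 9.19e-05, and unadjusted p = 0.0238 with an estimated correlation). Nkain4 went from 24.4 ± 0.862 to 9.87 ± 1.13, Upk3b from 4.39 ± 0.410 to 1.61 ± 0.327 and Gpm6a from 2.23 ± 0.147 to 0.807 ± 0.0871 FPKM. Ezr went from 9.03 ± 0.442 to 6.26 ± 0.564 and Aldh1a1 from 127 ± 5.51 to 99.7 ± 3.34 FPKM.

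The heptamer GAAGAAC in a 3′ UTR went with lower expression in siPfkfb3: it ranked first of 16088 heptamers on the lower side (z = −14.1, against at most 5.03 in absolute value over 100 shuffles), and 33.5% of its 1194 carriers were called lower against 19.2% of other genes, an excess of 170 genes or 7.54% of the lower calls searched. Unlike z, these shares and the excess were not adjusted for the length and GC content of the 3′ UTR. The excess is therefore not a measure of the heptamer's effect alone. Base composition is argued against, since the other 104 heptamers of the same bases reached no lower z than −3.05. Seed pairing of the Pfkfb3 siRNA is a candidate explanation. Medians, also unadjusted, were graded over genes with GAAGAACA (−0.12), with GAAGAAC alone (−0.06) and without it (−0.02), a difference of −0.10 between the first and last. GAAGAACA joins GAAGAAC and AAGAACA, which ranked 1 and 2 on the lower side of the same scan. The grading was thus partly set by that ranking and is not independent support. GAAGAACA occurs once in Pfkfb3, in coding exon 9 (chromosome 2, 11484317 to 11484324, minus strand, GRCm38; in 12 of 12 protein-coding transcripts). However, 18 of the 167 other octamers of these bases also occur in its longest coding transcript, and the siRNA's sequence is not given in the labels. On the higher side CGGAGAA ranked first (z = 8.79), and a widely used nontargeting duplex (sense strand TTCTCCGAACGTGTCACGT, recalled and not from the labels) has the seed matches TCGGAGA and TGTCACG, which ranked 4 and 10 (z = 6.77 and 5.15), so that repression by the control siRNA in the siScrambled samples is a candidate explanation. Other heptamers also passed the largest z of the shuffles, 3 in all on the lower side (AAGAACA, which also lies within GAAGAACA, at z = −10.0) and 10 on the higher (GGAGAAT and AGGAGAA at 6.98 and 6.79), and of the 5004 searched genes that carry none of these 13, 1746 (34.9%) were called, against 38.3% of the carriers.

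Interferon response genes were higher in siPfkfb3. Direct effects at the heptamer sites are argued against: the 27 members without GAAGAAC, CGGAGAA, TCGGAGA or TGTCACG had a median of 1.19, with a lower 95% bound of 0.82, and the 16 without any heptamer past the shuffles a median of 1.45. More leukocytes in the siPfkfb3 samples, as the cells that held these transcripts, are argued against too. The 19 leukocyte markers summed to at most 16.4 FPKM in siScrambled and at least 17.3 FPKM in siPfkfb3. Lyz2 made up most of the sum, and 16 markers stayed below 1 FPKM. The largest gain of the summed markers, 2.13 FPKM, was 0.409% of the smallest gain of the interferon list, 519 FPKM. An effect of a few leukocytes on the other cells was not tested. Sensing of the siRNA duplex by the cells, an indirect effect of off-target genes and an effect of losing Pfkfb3 cannot be told apart. The table holds neither untransfected cells nor a separate Pfkfb3 siRNA. Both groups received 20 nM of siRNA, so sensing would have to differ between the 2 siRNAs. The groups were 0.80 apart in mean log2(FPKM + 1) between their nearest libraries, which any of these could give.

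Cell cycle genes were lower in siPfkfb3. Pairing at GAAGAAC sites is argued against as the whole cause, since the 23 members without the heptamer had a median of −0.65, with an upper 95% bound of −0.56, and the 15 without any heptamer past the shuffles a median of −0.69 (upper bound −0.59). Scaling between libraries is argued against as well: the median stayed at −0.63 or lower under TPM, TMM and quantile scaling. An indirect effect of off-target genes and an effect of losing Pfkfb3 cannot be told apart with the siRNAs used, and the nearest libraries of the groups were 0.59 apart in mean log2(FPKM + 1), which either could give. The 5 mesothelial markers tested, of 19 listed, all fell in the same samples (median −0.84). Of 16 adventitial fibroblast markers 10 fell and 4 rose (camera, adjusted p = 0.119). Whether a change in the mix of cells bears on the cell cycle genes was not tested.

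The real split of the 6 samples gave 4079 called genes, and the highest of the other 9 gave 2. For gene lists at the preset correlation the real split gave 10 and the other splits 2 to 6. In both cases 1 of the 10 splits, the real one, gave a count as large, and 10 splits are too few for a share under 0.05. Each of the other 9 splits also mixes libraries of both groups. A group difference then widens the spread within their sides, which lowers their gene counts. Part of that difference remains between the sides and can give list calls. The other splits therefore do not show what would be called without a group difference.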
